A study of Mus musculus with 8 samples.

How the data were processed

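The samples were 8 liver RNA-seq libraries from wild-type C57BL/6 mice, 2 in each of 4 groups, after 30 weeks in a light/dark cycle or constant light and in filtered air or PM2.5. Per the labels, livers were snap-frozen, RNA was isolated with an RNeasy Micro kit and libraries followed the standard Illumina protocol. Nothing in the labels says that the replicates of a group came from separate animals, so the p-values may measure only the spread between samples. The time of day at collection, the sex of the mice, and dates or batches are not given in the sources used here. ATAC-seq, which the series description also mentions, was not analysed here.

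The submitters' processing notes name STAR, Cufflinks and Cuffdiff and the build mm10. Their versions, options and annotation release are not given in the sources used here. The deposited table of replicates holds, per the file headers, the fragments of each gene in each library as an expected or estimated count, and FPKM (fragments scaled to transcript length and sequencing depth) from the authors. Of the fragment values, 97.4% lay within 0.01 of a whole number, and they were rounded to whole numbers for the tests. The table lists 48432 genes. For 47 of them at least 1 library carried a status saying that no estimate was made, HIDATA in 172 entries and FAIL in 21. In 30 of the 47 genes HIDATA was the only such status, in 8 libraries for Alb and in 6 for Trf and Mup20. FAIL marked other genes, among them Hnf4a in 4 libraries. The 47 genes, with 1.07% of the listed fragments, were left out. HIDATA entries are listed with 0 fragments, so neither this share nor the library totals cover the RNA of those entries. FPKM and fragments of entries with the same symbol were added, which joined 62 genes and left 48323 symbols. Gene positions come from GENCODE vM21 on GRCm38/mm10. The 13 mitochondrially encoded transcripts stood at or near 0 and none was tested.

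Before the data were examined, the design was fixed as limma on log2(FPKM + 1) for FPKM, to be replaced by the edgeR quasi-likelihood test if the table held fragments per library, and this condition was met. Genes with at least 1 FPKM in at least 2 libraries were tested, 11316 in all. R 4.3.3, edgeR 4.0.16 (TMM scaling, a prior count of 2 for log2 CPM), limma 3.58.1, version 1.17.8 of data.table, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used. A single model with 4 group means and 4 residual degrees of freedom gave the 5 pairwise comparisons, the interaction, and the averages of PM2.5 over light and of light over air. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05, and fold changes are the first-named group over the second. The prior degrees of freedom were 3.46 and the biological coefficient of variation 21.4%. The standard error (SE) of a gene's log2 fold change was derived from the test. It is the absolute log2 fold change divided by the square root of the quasi-likelihood F. Its median was 0.19 between groups of 2 and 0.13 in the averages, which with 22215000 to 31819000 fragments per library sets the precision.

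Gene lists for pathways, rhythms and cell types, 39 in number, were also fixed before the data were examined. The 38 with tested members were tested with camera at a preset correlation of 0.01, with adjustment over lists within a comparison, beside camera with an estimated correlation and fry. Members were also adjusted over the list alone. The genes named were, for each pairwise comparison and direction, the 10 of largest fold change past the threshold with non-overlapping groups and a mean of at least 5 FPKM in either group. Where fewer passed, those of smallest unadjusted p, up to 5 per direction, are given as values that did not pass. To these come the members of both core clock lists, of which some are not reported here, and up to 4 members of smallest p per other list. Effects were set against each other by Pearson and Spearman correlation, with 100 simulations of unchanged groups that keep the shared libraries and draw genes independently.

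The alternatives planned were a pseudocount of 0.1 in place of 1 and quantile normalization (both limma on log2 FPKM), no filter, a stricter filter at 5 FPKM, median-of-ratios scaling, no variance trend, array weights, a replicate block, a fit of only the groups compared, an estimated correlation, and leaving out each library in turn. A group left with 1 library is then assumed to vary like the others. Added after seeing the data were limma with a trend on log2(FPKM + 1), DESeq2, a robust variance prior, a fit without LD-FA replicate 1 and LL-FA replicate 1, and exact permutation of list scores over the 70 arrangements of 4 against 4 libraries. The test was tried on simulated data with 200 changed genes, drawn independently for each gene at its estimated spread, with no library set apart. In the real data Saa1, at -5.62 for constant light in filtered air, was not called (edgeR adjusted p = 0.649). The simulated shares may therefore overstate the power. For PM2.5 in the light/dark cycle edgeR recovered 28.4% of genes changed 2-fold, 89.6% of those changed 4-fold and 100% of those changed 8-fold, and called 9 unchanged genes. DESeq2 recovered 58.2%, 94.0% and 95.5% and called 29 unchanged genes, and 14 where no gene was changed. A simulated shift of 1 in a list, with members drawn independently, had a camera adjusted p of 1.26e-16, and 0.0302 with an estimated correlation. With no list changed, camera called 1 of 38 lists at the preset correlation and 0 with an estimated one. Lists with correlated members were not simulated.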

Results

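Liver RNA was sequenced from wild-type C57BL/6 mice kept for 30 weeks under 1 of 4 conditions. A light/dark cycle (LD) or constant light (LL) was combined with filtered air (FA) or with fine particulate matter (PM2.5), airborne particles small enough to enter the deep lung. The groups LD-FA, LD-PM2.5, LL-FA and LL-PM2.5 held 2 libraries each, 8 in all. Estimated fragments per library, to 5 digits, came to 26851000 and 31819000 in LD-FA, 28026000 and 22215000 in LD-PM2.5, 25950000 and 22719000 in LL-FA, and 29758000 and 25832000 in LL-PM2.5. The design asks whether long exposure to polluted air disturbs the daily clock of the liver, with constant light as the known disturbance of that clock, and how both exposures combine. Of the 48432 genes listed, 11316 with at least 1 FPKM in at least 2 libraries were tested. Across genes, which are not independent replicates, the libraries of a group correlated with a Pearson r of 0.959 in LD-FA, 0.980 in LD-PM2.5, 0.959 in LL-FA and 0.968 in LL-PM2.5. A chi-square of each pair's fragments was 41.6 to 88.7 per degree of freedom, so no pair lay within sampling noise. Separate preparations of 1 animal could exceed that noise too, so this does not show separate animals. Each library was counted as 1 sample.

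Several libraries held transcripts of tissues other than liver. Cela2a, a digestive elastase made by the acinar cells of the pancreas, stood at 761 FPKM in LD-FA replicate 1, 22.3 in LD-PM2.5 replicate 1 and 71.2 in LL-PM2.5 replicate 2. In the other 5 libraries it lay between 0.101 and 1.5 FPKM. The 7 measured pancreas markers summed to 2921 FPKM in LD-FA replicate 1, 86.7 in LD-PM2.5 replicate 1 and 280.7 in LL-PM2.5 replicate 2, against 0.393 to 4.56 elsewhere. Acta1, the actin of skeletal muscle fibres, was at 88.4 FPKM in LD-FA replicate 1, 10.2 in LD-FA replicate 2 and 171 in LL-FA replicate 1, and at most 0.204 in the other 5. The 6 muscle markers summed to 223.5, 24.6 and 422.7 FPKM in those 3 libraries and to 0.513 to 1.17 in the rest. Adipoq, a hormone secreted by fat cells, reached 6.94 FPKM in LL-FA replicate 1 and at most 0.898 elsewhere. The mean of the muscle transcripts is therefore higher in filtered air in both light regimes. In constant light this rests on LL-FA replicate 1 alone, since LL-FA replicate 2 summed to 0.695 FPKM.

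**Figure D1:**
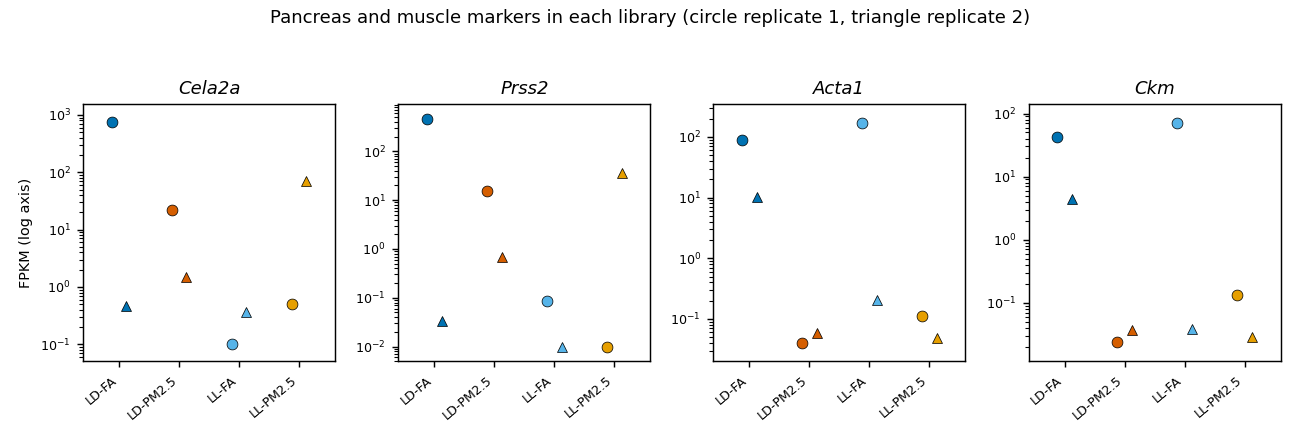
FPKM of 2 pancreas markers (Cela2a, Prss2) and 2 muscle markers (Acta1, Ckm) in each of the 8 libraries, on log axes, with values under 0.01 drawn at 0.01. Circles are replicate 1 and triangles replicate 2. Pancreas markers peak in LD-FA replicate 1 (Cela2a at 761) and muscle markers in LL-FA replicate 1 (Acta1 at 171).

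The first comparison, LD-PM2.5 against LD-FA, asks what PM2.5 did under a normal light/dark cycle. Transcripts that the clock proteins CLOCK and BMAL1 switch on through E-box elements stood higher in LD-PM2.5. Dbp, a clock-driven transcription factor (chromosome 7, 45705088 to 45710203, GRCm38/mm10), averaged 11.1 ± 2.74 FPKM (SD, n = 2) against 2.41 ± 0.509 in LD-FA, a log2 fold change of 2.21 ± 0.39 (SE). Adjusted over the list alone, 7 of the 11 measured E-box driven clock genes rose and none fell, among them the clock repressors Per1 at 1.67 ± 0.55, Per2 at 2.21 ± 0.70 and Per3 at 3.34 ± 0.77, and Tef at 1.59 ± 0.41. The median of the list was 1.59, and it passed camera (adjusted p = 5.11e-09, and adjusted p = 0.579 with an estimated correlation). In the list of clock genes that peak at the opposite phase, Arntl, which encodes BMAL1 (chromosome 7, 113207465 to 113314126), fell by 0.65 ± 0.14 and its partner gene Npas2 stood at -2.52 ± 0.83, while the repressor Nfil3 rose by 0.66 ± 0.17, each adjusted over the list alone. That list did not pass camera (adjusted p = 0.795, median 0.36, 7 measured). The LD-PM2.5 libraries differed from each other in clock genes. Replicates 1 and 2 read 52.5 and 5.55 FPKM for Nr1d1, 1.85 and 9.33 for Per2 and 2.85 and 15.1 for Cry1. Without LD-PM2.5 replicate 2 the E-box median was 0.66, with Per1 at 0.57, Per2 at 0.66, Per3 at 1.5 and Tef at 0.70. Npas2 was -5.50 without LD-PM2.5 replicate 1 and -1.66 without replicate 2.

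**Figure D2:**
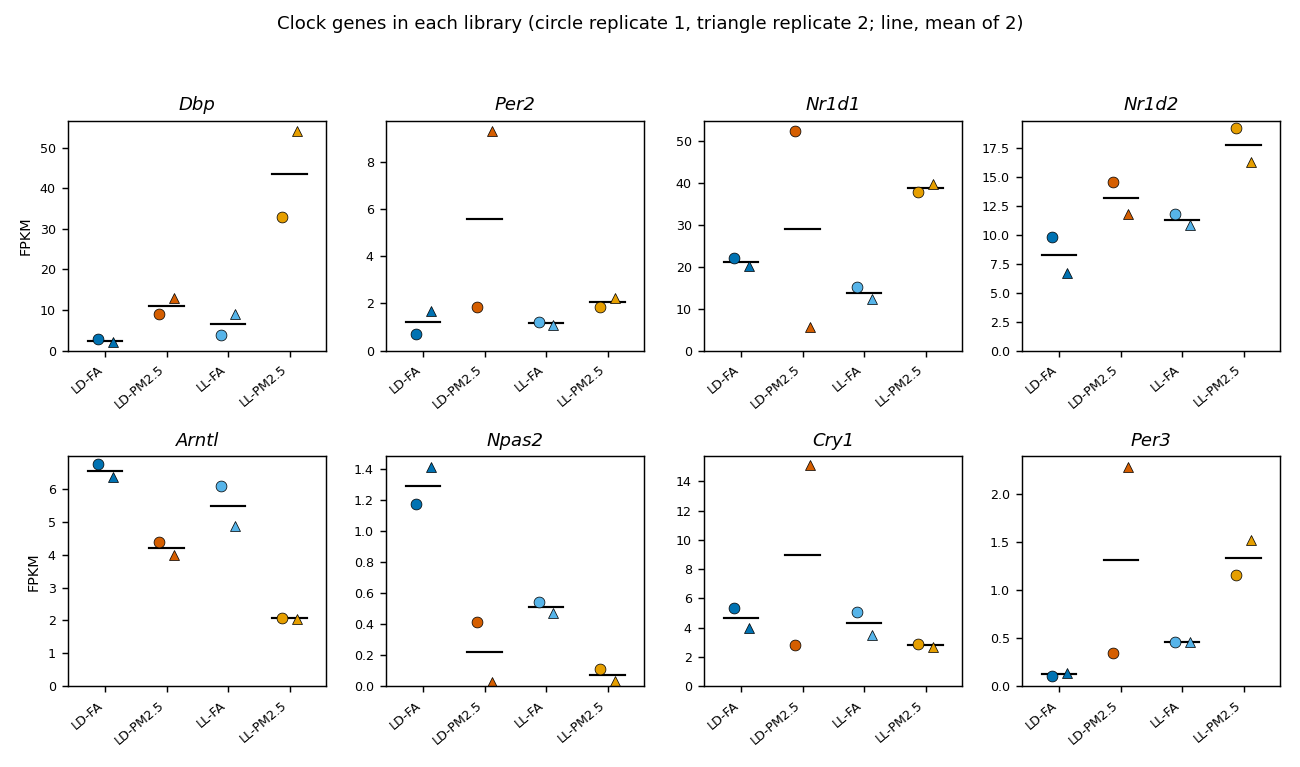
FPKM of 8 clock genes in each of the 8 libraries on linear axes. Circles are replicate 1, triangles replicate 2 and lines the mean of both. Arntl is lowest in LL-PM2.5 (2.09 and 2.04 FPKM) and Dbp highest there (32.9 and 54.0), and the LD-PM2.5 libraries stand apart from each other for Nr1d1, Per2, Per3 and Cry1.

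Other lists passed camera for PM2.5 in the light/dark cycle. Hemoglobin transcripts, carried by red blood cells, were lower, with Hba-a1 (chromosome 11, 32283511 to 32284465) at 5.37 ± 0.782 FPKM against 18.2 ± 7.75. Adjusted over the list alone, 4 of the 5 measured erythroid genes fell and none rose, Hba-a1 by 1.73 ± 0.31 and Hbb-bs by 1.44 ± 0.36 on the log2 scale (camera adjusted p = 1.58e-07, and adjusted p = 0.579 with an estimated correlation). The erythroid median moved from -1.44 to -0.68 without LD-FA replicate 1, where Hbb-bs stood at -0.67. Of 9 measured cytokine and NF-kB genes, 3 rose adjusted over the list alone, namely the neutrophil attractant Cxcl1 at 3.04 ± 0.63, the cytokine-signalling brake Socs3 at 3.12 ± 0.81 and the adhesion molecule Icam1 at 1.08 ± 0.31 (camera adjusted p = 0.000139, and adjusted p = 0.579 with an estimated correlation). Without LD-PM2.5 replicate 2, Icam1 stood at 0.58 and the median of the list went from 0.88 to 0.58. The neutrophil genes S100a8 at 1.14 ± 0.44 and S100a9 at 1.02 ± 0.43 rose adjusted over the list alone (camera adjusted p = 0.0454, and adjusted p = 0.579 with an estimated correlation), with 0.48 and 0.29 without LD-PM2.5 replicate 2, and their camera call ended without LD-FA replicate 2 (adjusted p = 0.195), LD-PM2.5 replicate 2 (0.437), LL-PM2.5 replicate 1 (0.0537) or LL-PM2.5 replicate 2 (0.0519). Cholesterol synthesis genes had a negative fold change in 22 of 24 cases, and none passed the test adjusted over the list alone (camera adjusted p = 6.02e-11, and adjusted p = 0.579 with an estimated correlation). Their median of -0.74 was -1.35 without LD-PM2.5 replicate 1 and -0.26 without LD-PM2.5 replicate 2. Among rhythmic liver outputs, Rgs16, a regulator of G protein signalling, rose by 2.59 ± 0.37 and Alas1, the first enzyme of heme synthesis, by 1.93 ± 0.43, while the cell cycle inhibitor Cdkn1a fell by 0.86 ± 0.24. In that list 6 of 13 measured genes rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00481, and adjusted p = 0.579 with an estimated correlation), and its camera call ended without LD-PM2.5 replicate 2 (adjusted p = 0.471). Heat shock genes had a median of 0.65 with 0 of 14 past the test adjusted over the list alone (camera adjusted p = 0.000163, and adjusted p = 0.622 with an estimated correlation, and a median of 0.42 without LD-PM2.5 replicate 2). Muscle transcripts were lower in the same comparison, with the 6 markers summing to 0.513 and 0.826 FPKM in LD-PM2.5.

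Over all genes, edgeR called 0 of 11316 for PM2.5 in the light/dark cycle, with a smallest adjusted p of 0.324. At an unadjusted p under 0.05 there were 1240 genes, 767 higher and 473 lower, where chance alone gives 566 on average. Over splits of the 8 libraries 4 against 4, described below, such counts ran from 113 to 2193. A count above 566, here or in the comparisons below, is therefore not by itself an excess over chance. DESeq2 called 151, 109 up and 42 down, of which 4 were markers of pancreas, muscle or fat. The genes of smallest p by the rule fixed in advance, none past the threshold, included the actin-binding protein Mtss1 at 1.46 ± 0.16, the kinases Pim1 at 1.09 ± 0.16 and Pim3 at 1.35 ± 0.20, and the phosphatidate phosphatase Lpin2 at 1.08 ± 0.17. On the lower side stood Fam89a at -1.12 ± 0.17 and the histidine-degrading enzyme Hal at -0.73 ± 0.14. In 5591 genes (49.4%) both libraries of 1 group lay beyond both of the other, where chance gives 33.3%. Camera called 12 of 38 lists, 8 up and 4 down, and 6 of the calls held without each library in turn. With an estimated correlation camera called 0 lists in this and in each of the 7 other comparisons, and so did fry's test for a shared direction. Here the estimate was 0.33 for E-box driven, 0.56 for cholesterol synthesis and 0.69 for heat shock genes, far above the preset 0.01. Camera p-values at the preset correlation may be too small for such lists. Some uncalled lists were under 0.01, such as NRF2 antioxidant (0.0060), cell cycle (-0.0016) and sinusoidal endothelium genes (0.0010). Whether the higher correlation alone ended the calls was not tested. Fry's mixed test, which takes changes in either direction, called 2 lists for PM2.5 in constant light. These were opposite phase clock genes (adjusted p = 0.00449) and rhythmic liver outputs (0.0384). It called 2 lists for both exposures, 2 for constant light averaged over air and 1 for PM2.5 averaged over light. For PM2.5 in the light/dark cycle, as in the remaining comparisons, it called 0. Without LD-PM2.5 replicate 1 edgeR called 36 genes, 24 up and 12 down.

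The second comparison, LL-FA against LD-FA, asks what constant light did in clean air. Transcripts of some acute phase proteins, which hepatocytes secrete into blood during inflammation, fell in constant light. Serum amyloid Saa1 (chromosome 7, 46740497 to 46742980) averaged 41.8 ± 2.70 FPKM (SD, n = 2) against 2066 ± 1110.2, a log2 fold change of -5.62 ± 0.98 (SE). Of 24 measured acute phase genes 9 fell and none rose adjusted over the list alone, including Saa2 at -5.73 ± 1.19, the iron-carrier binder Lcn2 at -4.17 ± 0.90 and Orm2 at -2.43 ± 0.45. The list passed camera (adjusted p = 3.50e-31, and adjusted p = 0.155 with an estimated correlation), and its median of -0.74 was -0.36 without LD-FA replicate 1, the library with 2921 FPKM of pancreas markers where the LL-FA libraries held 0.393 and 0.455. Inducible chaperones were lower as well. Hspa1a fell by 3.61 ± 0.48, Hspa1b (chromosome 17, 34956436 to 34959238) by 3.0 ± 0.52 and Dnajb1 by 1.09 ± 0.19, 3 of 14 measured heat shock genes adjusted over the list alone, with none up (camera adjusted p = 5.34e-15, and adjusted p = 0.290 with an estimated correlation). Cytokine and NF-kB genes fell in 5 of 9 cases adjusted over the list alone, among them the cytokine Il1b at -2.15 ± 0.32 and the chemokine Ccl2 at -2.23 ± 0.61 (camera adjusted p = 1.67e-16, and adjusted p = 0.155 with an estimated correlation).

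**Figure D3:**
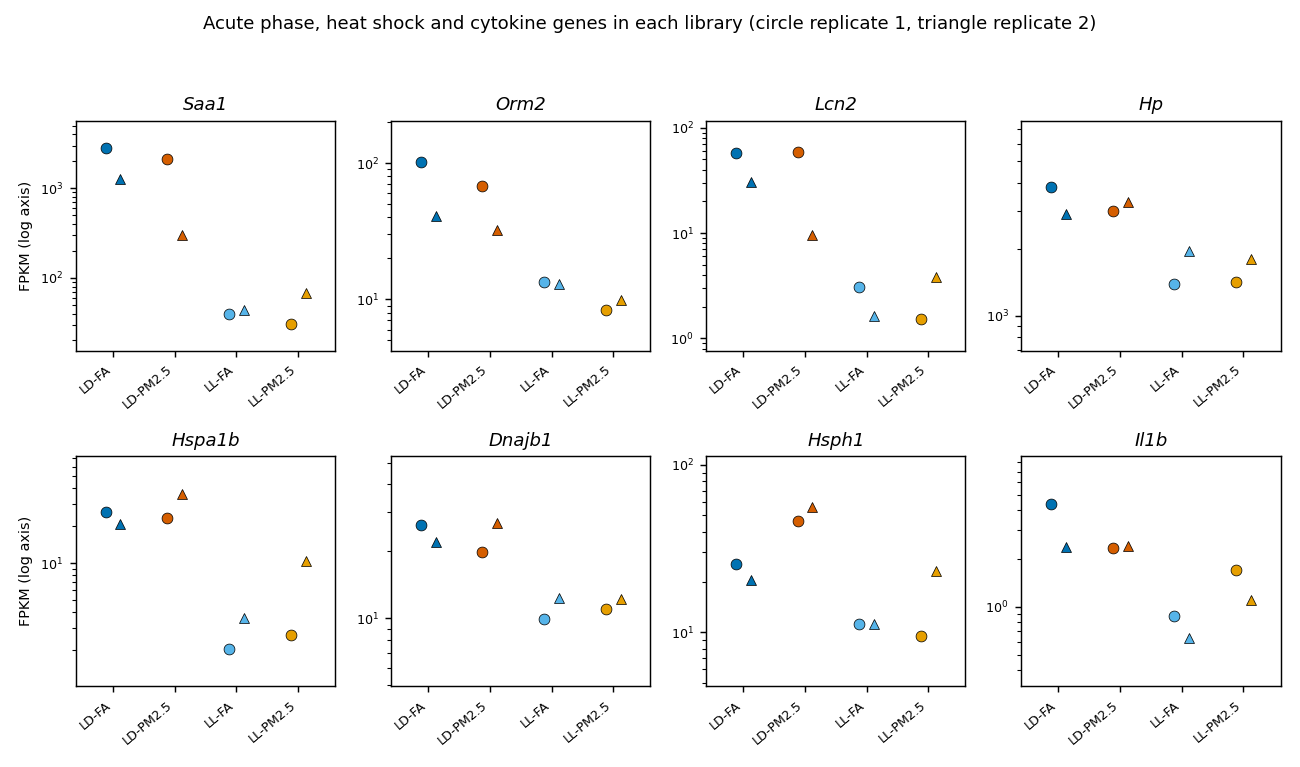
FPKM of 4 acute phase genes (top), 3 heat shock genes and the cytokine gene Il1b (bottom) in each of the 8 libraries, on log axes that differ between panels. Circles are replicate 1 and triangles replicate 2. Saa1 lies between 30.9 and 68.5 FPKM in the 4 constant light libraries and between 303 and 2851 in the 4 light/dark libraries.

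Fatty acid oxidation genes and PPARa targets had a positive fold change in constant light in 22 of 23 measured cases. None passed the test adjusted over the list alone, and the list passed camera (adjusted p = 3.83e-13, and adjusted p = 0.290 with an estimated correlation) with a median of 0.35. The median was 0.21 without LD-FA replicate 1 and LL-FA replicate 1. Adipocyte markers passed camera on the higher side in the same comparison (adjusted p = 8.76e-05, and adjusted p = 0.290 with an estimated correlation), and not without LL-FA replicate 1 (adjusted p = 0.629). The immunoglobulin heavy chain Ighm, a product of B cells, fell by 1.48 ± 0.21, and Jchain, which links antibody units, stood at -1.40 ± 0.41, 2 of 3 measured B and plasma cell markers adjusted over the list alone (camera adjusted p = 4.13e-09, and adjusted p = 0.186 with an estimated correlation). Jchain was -0.75 without LD-FA replicate 1, and the median of the markers went from -1.40 to -0.75. E-box driven clock genes were positive in 8 of 11 cases with none past the test adjusted over the list alone (camera adjusted p = 7.03e-05, and adjusted p = 0.306 with an estimated correlation). Their median of 0.29 was 0.58 without LD-FA replicate 2, 0.14 without LL-FA replicate 1 and 0.43 without LL-FA replicate 2. Interferon response genes were negative in 18 of 18 cases (camera adjusted p = 1.18e-07, and adjusted p = 0.309 with an estimated correlation), and the call ended without LL-FA replicate 1 (adjusted p = 0.0676). The list of macrophage markers also passed camera (adjusted p = 4.76e-05, and adjusted p = 0.402 with an estimated correlation) and lost its call without LL-FA replicate 1 (adjusted p = 0.928), the library richest in muscle and fat transcripts.

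No gene was called by edgeR for constant light in filtered air (0 of 11316, smallest adjusted p 0.515), and 310 had an unadjusted p under 0.05, 135 higher and 175 lower, where chance gives 566. DESeq2 called 43, 10 up and 33 down, of which 4 were markers of pancreas, muscle or fat. By the fixed rule the genes of smallest p, none past the threshold, were led by the retinoic acid hydroxylase Cyp26a1 at 2.14 ± 0.32, Etfbkmt at 1.53 ± 0.27 and the taurine-synthesis enzyme Csad at 0.93 ± 0.18 on the higher side. Ighm, Prg4 at -1.16 ± 0.18 and Dnajb1 led the lower side. Non-overlapping groups were seen in 3412 genes (30.2%), against 33.3% by chance. Camera called 18 lists, 4 up and 14 down, of which 6 held without each library in turn.

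PM2.5 under constant light, LL-PM2.5 against LL-FA, asks whether the particles acted on animals already without a light cycle. Clock genes again stood apart. Dbp averaged 43.5 ± 15.0 FPKM (SD, n = 2) against 6.47 ± 3.69, a log2 fold change of 2.82 ± 0.38 (SE), and Arntl 2.06 ± 0.0361 against 5.49 ± 0.863, a change of -1.37 ± 0.15. All 11 measured E-box driven genes had a positive fold change with a median of 0.82. Adjusted over the list alone, Dbp and the nuclear receptor Nr1d2 at 0.67 ± 0.17 rose, while Per1 at 0.95 ± 0.54, Per3 at 1.53 ± 0.69 and Nr1d1 at 1.5 ± 0.80 did not pass (camera adjusted p = 3.16e-11, and adjusted p = 0.254 with an estimated correlation). Per1 was 0.53 without LL-PM2.5 replicate 1. Of the 7 opposite phase genes 6 were negative and Arntl fell adjusted over the list alone (camera adjusted p = 1.11e-06, and adjusted p = 0.254 with an estimated correlation). The median of that list, -0.39, was -0.62 without LL-PM2.5 replicate 1 and -0.20 without LL-PM2.5 replicate 2. Rgs16 rose by 4.54 ± 0.43 and Cdkn1a fell by 1.97 ± 0.25 adjusted over the list of rhythmic outputs alone, which as a whole did not pass camera (adjusted p = 0.929).

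Of 15 genes of glucose handling and the insulin response, 12 had a positive fold change with PM2.5 in constant light. Adjusted over the list alone the insulin receptor substrate Irs2 rose by 1.77 ± 0.32 and the insulin-repressed Igfbp1 by 3.6 ± 0.85 (camera adjusted p = 3.51e-08, and adjusted p = 0.254 with an estimated correlation). Igfbp1 was at 9.55 and 56.1 FPKM in the LL-PM2.5 libraries, and its change was 1.72 without LL-PM2.5 replicate 2. In the bile acid list the sterol exporters Abcg5 at 1.33 ± 0.26 and Abcg8 at 0.94 ± 0.18 rose and Cyp8b1, the enzyme that directs synthesis to cholic acid, fell by 1.02 ± 0.24, adjusted over the list alone. The list itself did not pass camera (adjusted p = 0.963). Hemoglobin genes rose here, 4 of 5 measured erythroid genes adjusted over the list alone, with Hba-a1 at 1.12 ± 0.30 and Hbb-bs at 1.06 ± 0.36 (camera adjusted p = 9.25e-07, and adjusted p = 0.254 with an estimated correlation). Female-biased liver genes had a median of 0.90 over 4 measured members, which was 0.55 without LL-PM2.5 replicate 2 (camera adjusted p = 0.000107, and adjusted p = 0.254 with an estimated correlation), and male-biased genes one of -0.28 (camera adjusted p = 0.00208, and adjusted p = 0.323 with an estimated correlation), with 0 members of either past the test adjusted over the list alone. Pancreas transcripts were higher in LL-PM2.5 replicate 2 and muscle and fat transcripts in LL-FA replicate 1. The lists of muscle and fat markers passed camera in this comparison (adjusted p = 6.02e-06 and 0.00125, and adjusted p = 0.405 and 0.323 with an estimated correlation), and neither passed without LL-FA replicate 1 (adjusted p = 0.617 and 0.753).

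Across all genes edgeR called 0 of 11316 for PM2.5 in constant light (smallest adjusted p 0.113, for Rgs16), with 547 at an unadjusted p under 0.05, 240 higher and 307 lower, and 566 given by chance. DESeq2 called 58, 31 up and 27 down, of which 5 were markers of pancreas, muscle or fat. The fixed rule named, as values that did not pass, the hepcidin gene Hamp2 at 3.38 ± 0.56, Klf15, a regulator of amino acid breakdown, at 0.62 ± 0.12, the major urinary protein Mup9 at -5.02 ± 0.98 and the mitochondrial chaperone Clpx at -1.07 ± 0.21. Groups did not overlap in 3410 genes (30.1%), against 33.3% by chance. Camera called 16 lists, 10 up and 6 down, and 6 held without each library. Without LL-PM2.5 replicate 1 edgeR called 10 genes, 4 up and 6 down, and without LL-PM2.5 replicate 2 it called Rgs16 (adjusted p = 0.0496).

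Constant light among PM2.5-exposed animals, LL-PM2.5 against LD-PM2.5, gave the broadest fall of chaperone genes. All 14 measured heat shock genes had a negative fold change and 10 fell adjusted over the list alone, with none up. Hspa1b averaged 6.49 ± 5.45 FPKM (SD, n = 2) against 29.7 ± 9.38, a log2 fold change of -2.21 ± 0.49 (SE), with Hsp90aa1 at -1.42 ± 0.34 and Dnajb1 at -0.98 ± 0.19. Hsph1, at -1.56 ± 0.44, was -0.99 without LL-PM2.5 replicate 1 and -2.53 without LL-PM2.5 replicate 2. The list passed camera (adjusted p = 1.09e-16, and adjusted p = 0.310 with an estimated correlation) with a median of -0.93. Acute phase genes fell in 10 of 24 cases adjusted over the list alone, with Orm2 at -2.44 ± 0.45, Hp at -0.93 ± 0.23 and Serpina3n at -1.01 ± 0.24 (camera adjusted p = 4.77e-14, and adjusted p = 0.263 with an estimated correlation). Saa1, at -4.59 ± 0.93, was -2.63 without LD-PM2.5 replicate 1, and the median of the list went from -0.61 to -0.41. Of the 9 cytokine and NF-kB genes 4 fell adjusted over the list alone, including Cxcl1 at -3.56 ± 0.65 and Icam1 at -1.68 ± 0.32 (camera adjusted p = 2.99e-11, and adjusted p = 0.184 with an estimated correlation), and their median of -1.26 was -0.70 without LD-PM2.5 replicate 2.

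Other lists in this comparison included the clock, blood cells and liver zones. All 7 opposite phase clock genes were negative, and Arntl fell by 0.99 ± 0.15 and Nfil3 by 1.21 ± 0.17 adjusted over the list alone (camera adjusted p = 2.44e-07, and adjusted p = 0.184 with an estimated correlation). The median of -1.21 was -0.69 without LD-PM2.5 replicate 2. Dbp rose by 2.03 ± 0.37, 1 of 11 E-box driven genes adjusted over the list alone, and that list did not pass camera (adjusted p = 0.127). Hemoglobin genes rose, 4 of 5 erythroid markers adjusted over the list alone, with Hba-a1 at 2.07 ± 0.31 and Hbb-bs at 1.77 ± 0.36 (camera adjusted p = 2.33e-12, and adjusted p = 0.184 with an estimated correlation). The neutrophil granule genes S100a8 at -1.76 ± 0.45 and S100a9 at -1.41 ± 0.44 fell adjusted over the list alone (camera adjusted p = 0.00106, and adjusted p = 0.368 with an estimated correlation). They were -1.10 and -0.67 without LD-PM2.5 replicate 2. Pericentral hepatocyte genes, which mark the zone around the central vein, had a median of -0.46, -0.92 without LL-PM2.5 replicate 1 and -0.11 without LL-PM2.5 replicate 2 (camera adjusted p = 0.00306, and adjusted p = 0.629 with an estimated correlation), and the call ended without LL-PM2.5 replicate 2 (adjusted p = 0.421) and without LD-PM2.5 replicate 1 (adjusted p = 0.115). That LL-PM2.5 library held 159 FPKM of Glul, the pericentral glutamine synthetase, where the other 7 held 335 to 499, and it was the library of its group with pancreas transcripts. Periportal genes, of the opposite zone, had a median of 0.34 with 2 of 10 up adjusted over the list alone (camera adjusted p = 0.0218, and adjusted p = 0.629 with an estimated correlation), and the median was 0.17 without LD-PM2.5 replicate 1, 0.54 without LD-PM2.5 replicate 2, 0.55 without LL-PM2.5 replicate 1 and 0.093 without LL-PM2.5 replicate 2. Their call ended without LD-PM2.5 replicate 1 (adjusted p = 0.513) and without LL-PM2.5 replicate 2 (0.227). Camera also called cholesterol synthesis genes as higher (adjusted p = 9.15e-06) and, as lower, unfolded protein response (0.000416), immediate early (0.00134), male-biased (0.00418) and DNA and histone methylation genes (0.0234), with adjusted p from 0.383 to 0.714 with an estimated correlation. These calls ended, in the same order, without LD-PM2.5 replicate 2 (adjusted p = 0.704), without LD-PM2.5 replicate 1 (0.644) or LL-PM2.5 replicate 1 (0.863), without LD-PM2.5 replicate 2 (0.121) or LL-PM2.5 replicate 1 (0.790), without LD-PM2.5 replicate 1 (0.567), and without LD-PM2.5 replicate 1 (0.188) or LL-PM2.5 replicate 2 (0.421).

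edgeR called 0 of 11316 genes for constant light in PM2.5 (smallest adjusted p 0.349), and 1044 had an unadjusted p under 0.05, 401 higher and 643 lower, against 566 by chance. DESeq2 called 139, 33 up and 106 down. Named by the rule without passing were Hamp2 at 3.24 ± 0.56, Cyp26a1 at 1.74 ± 0.32, the macrophage growth factor Csf1 at -1.62 ± 0.25 and the co-chaperone Bag3 at -1.22 ± 0.21. In 4469 genes (39.5%) the groups did not overlap, against 33.3% by chance. Camera called 13 lists, 3 up and 10 down, 6 of which held without each library. The count of genes was 1 without LD-PM2.5 replicate 1 (Tppp) and 4 without LL-PM2.5 replicate 1 (Acnat2, Mup1, Mup12 and Serpina12), named here after their values were seen.

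Both exposures together, LL-PM2.5 against LD-FA, gave the largest fold changes of Dbp and Arntl among the pairwise comparisons. Dbp averaged 43.5 ± 15.0 FPKM (SD, n = 2) against 2.41 ± 0.509, a log2 fold change of 4.24 ± 0.41 (SE), and Arntl 2.06 ± 0.0361 against 6.55 ± 0.286, a change of -1.64 ± 0.15. Both had an edgeR adjusted p of 0.0642 over all genes. Of 11 E-box driven genes 5 rose adjusted over the list alone, Dbp, Per3 at 3.44 ± 0.77, Ciart at 3.34 ± 0.90, Tef at 1.81 ± 0.41 and Nr1d2 at 1.08 ± 0.17 (camera adjusted p = 3.81e-18, and adjusted p = 0.180 with an estimated correlation). Of the 7 opposite phase genes 3 fell, Arntl, Npas2 at -4.07 ± 0.93 and Nfil3 at -0.55 ± 0.17 (camera adjusted p = 1.87e-07, and adjusted p = 0.180 with an estimated correlation). Acute phase genes fell in 9 of 24 cases adjusted over the list alone, with Saa1 at -5.36 ± 0.96 and Orm2 at -2.96 ± 0.46 (camera adjusted p = 9.49e-17, and adjusted p = 0.180 with an estimated correlation). Of the 10 pericentral genes 5 fell adjusted over the list alone, including Glul at -0.84 ± 0.28, the ammonium transporter Rhbg at -1.42 ± 0.22 and Lgr5 at -0.81 ± 0.18 (camera adjusted p = 3.51e-08, and adjusted p = 0.225 with an estimated correlation). Glul was -1.38 without LL-PM2.5 replicate 1 and -0.44 without LL-PM2.5 replicate 2. The median of these genes, -0.54, was -1.02 without LL-PM2.5 replicate 1 and -0.19 without LL-PM2.5 replicate 2. Periportal genes had a median of 0.35 with 1 of 10 up adjusted over the list alone (camera adjusted p = 0.00978, and adjusted p = 0.447 with an estimated correlation), 0.11 without LL-PM2.5 replicate 2, and the call ended without LD-FA replicate 2 (adjusted p = 0.0841) or LL-PM2.5 replicate 2 (0.206). Acot3, an acyl-CoA thioesterase of the female-biased list, rose by 2.75 ± 0.45 (camera adjusted p = 1.25e-06, and adjusted p = 0.180 with an estimated correlation), and Selenbp2 of the male-biased list fell by 2.08 ± 0.45 (camera adjusted p = 2.98e-06, and adjusted p = 0.180 with an estimated correlation), 1 of 4 and 1 of 11 adjusted over the list alone. Without LL-PM2.5 replicate 2 the median of the female-biased list went from 1.22 to 0.54 and that of the male-biased list from -0.64 to -0.38, the latter being -0.41 without LD-FA replicate 1.

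edgeR called 0 of 11316 genes for both exposures, with 759 at an unadjusted p under 0.05, 340 higher and 419 lower, against 566 by chance, and DESeq2 called 95, 35 up and 60 down. The rule also named Cdkn1a at -2.16 ± 0.25, the inflammation-induced glycoprotein Lrg1 at -1.61 ± 0.24 and the ceramide glucosyltransferase Ugcg at 0.88 ± 0.14, none past the threshold. Groups did not overlap in 4117 genes (36.4%), against 33.3% by chance. Muscle markers were lower in LL-PM2.5 and pancreas markers stood at 2921 FPKM in 1 of the LD-FA libraries. Camera called 19 lists, 8 up and 11 down, of which 8 held without each library, and 12 lists without LL-PM2.5 replicate 1. The count of genes was 1 without LD-PM2.5 replicate 1 (Per3) and 7, 2 up and 5 down, without LL-PM2.5 replicate 1. It was 2 with a stricter filter (Arntl and Dbp) and 1 with a robust prior (Arntl).

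**Figure D4:**
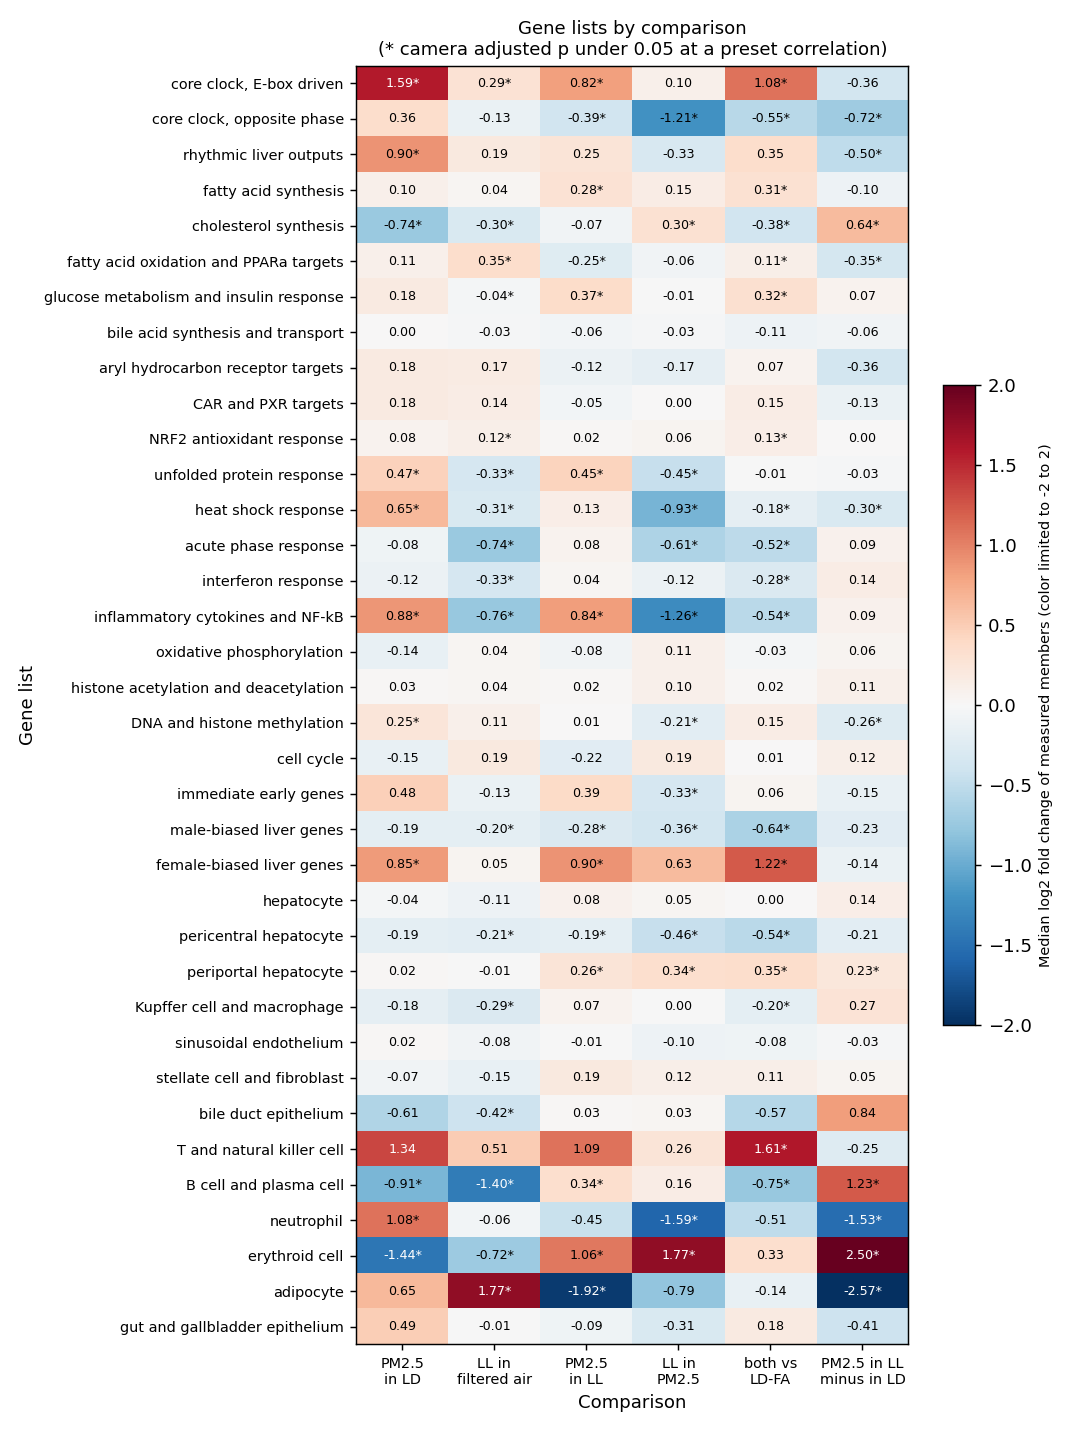
Median log2 fold change of each gene list in 6 comparisons, with the number in each cell and an asterisk where camera at a preset correlation had an adjusted p under 0.05. Colours are limited to -2 to 2, and the pancreas and muscle lists are left out. E-box driven clock genes are highest for PM2.5 in the light/dark cycle (1.59) and heat shock genes lowest for constant light in PM2.5 (-0.93).

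The interaction, the effect of PM2.5 in constant light minus that in the light/dark cycle, asks whether the particles acted differently in each light regime. Erythroid genes had the smallest camera p of the lists, and hemoglobin genes fell with PM2.5 in the light/dark cycle and rose with it in constant light. In the erythroid list 4 of 5 genes differed adjusted over the list alone, Hba-a1 by a log2 change of 2.85 ± 0.43 (SE, n = 2 per group) and Hbb-bs by 2.5 ± 0.51 (camera adjusted p = 2.49e-16, and adjusted p = 0.263 with an estimated correlation). Cholesterol synthesis genes had a positive difference in 23 of 24 cases, with none past the test adjusted over the list alone (camera adjusted p = 4.46e-09, and adjusted p = 0.649 with an estimated correlation). Their median of 0.64 was 1.41 without LD-PM2.5 replicate 1 and 0.17 without LD-PM2.5 replicate 2. All 7 opposite phase clock genes had a negative difference, past the test adjusted over the list alone for Arntl at -0.72 ± 0.20 and Nfil3 at -0.92 ± 0.24 (camera adjusted p = 0.000448, and adjusted p = 0.538 with an estimated correlation). The E-box driven list did not pass camera for the interaction (adjusted p = 0.555). The B and plasma cell genes Ighm at 1.23 ± 0.29 and Jchain at 1.55 ± 0.58 also differed adjusted over the list alone (camera adjusted p = 0.000437, and adjusted p = 0.538 with an estimated correlation), with Jchain at 0.91 without LD-FA replicate 1. Heme synthesis Alas1, at -3.26 ± 0.61, went up with PM2.5 in the light/dark cycle and down with it in constant light. Its change in constant light was -0.64 without LL-FA replicate 2 and -1.33 with it. edgeR called 0 of 11316 genes for the interaction (smallest adjusted p 0.843), 552 had an unadjusted p under 0.05, and DESeq2 called 33, 17 up and 16 down. Camera called 12 lists, 5 up and 7 down, and 4 held without each library.

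Averaged over both light regimes, PM2.5 raised 2 genes past the edgeR threshold over all genes. Rgs16 (chromosome 1, 153740349 to 153745468, GRCm38/mm10) was higher by a log2 fold change of 3.56 ± 0.29 (SE, n = 4 libraries per side, edgeR adjusted p = 0.0337), from 0.0880 to 0.350 FPKM in the 4 filtered air libraries to between 1.61 and 3.30 in the 4 PM2.5 libraries. Mtss1, an actin-binding protein of the cell membrane (chromosome 15, 58941234 to 59082005), was higher by 1.25 ± 0.11 (edgeR adjusted p = 0.0408), from 13.1 to 15.2 FPKM in filtered air to between 29.7 and 41.8 with PM2.5. Of the E-box driven clock genes 7 of 11 rose adjusted over the list alone, led by Dbp at 2.51 ± 0.27 (camera adjusted p = 2.00e-16, and adjusted p = 0.30 with an estimated correlation), and the median of 1.2 was 0.76 without LD-PM2.5 replicate 2. The mean log2 level of the list was higher in 16 of 16 pairs of a PM2.5 and a filtered air library, by 1.12 (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 libraries can give, and adjusted p = 0.543 over 38 lists). For the opposite phase list the median of 0.18 was positive while the mean of -0.38 and camera were negative (adjusted p = 0.0211, and adjusted p = 0.487 with an estimated correlation), and the camera call ended without LD-PM2.5 replicate 1 (adjusted p = 0.328), LD-FA replicate 2 (0.103), LL-FA replicate 1 (0.109) or LL-PM2.5 replicate 2 (0.0722). All 15 glucose and insulin genes were positive, with Irs2 at 1.24 ± 0.22 and the gluconeogenic enzyme Pck1 at 0.77 ± 0.16 past the test adjusted over the list alone (camera adjusted p = 3.21e-06, and adjusted p = 0.30 with an estimated correlation). Muscle markers were lower with PM2.5 in the same average. When the 8 libraries were split 4 against 4 in other ways, in a model of 2 groups, 20 of 35 splits gave as many lists past camera as the real split's 13. The number of genes called was 0 without LD-FA replicate 1, LD-FA replicate 2, LD-PM2.5 replicate 2, LL-FA replicate 1 or LL-FA replicate 2, 17 without LD-PM2.5 replicate 1, 10 without LL-PM2.5 replicate 1 and 1 (Rgs16) without LL-PM2.5 replicate 2. It was 0 without both LD-FA replicate 1 and LL-FA replicate 1 or with a stricter filter, and DESeq2 called 161, 78 up and 83 down, including 7 markers of pancreas, muscle or fat.

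Averaged over both kinds of air, constant light came with lower levels of some acute phase, chaperone and cytokine transcripts. Of 24 acute phase genes 9 fell adjusted over the list alone, Saa1 by 5.10 ± 0.67 (SE, n = 4 libraries per side) and Orm2 by 2.44 ± 0.32 (camera adjusted p = 3.63e-37, and adjusted p = 0.108 with an estimated correlation). In the heat shock list 8 of 14 fell, Hspa1a by 2.91 ± 0.33 and Hspa1b by 2.60 ± 0.36 (camera adjusted p = 5.25e-30, and adjusted p = 0.158 with an estimated correlation), and in the cytokine list 7 of 9, Cxcl1 by 2.74 ± 0.46 and Il1b by 1.46 ± 0.22 (camera adjusted p = 4.64e-25, and adjusted p = 0.108 with an estimated correlation). Markers of neutrophils (adjusted p = 0.00418), of B and plasma cells (0.00418) and of macrophages (0.00689) passed camera on the lower side too, with 2 of 2, 1 of 3 and 0 of 14 down adjusted over the list alone and adjusted p of 0.366, 0.366 and 0.569 with an estimated correlation. The calls ended for neutrophils without LD-PM2.5 replicate 2 (adjusted p = 0.0678), for B and plasma cells without LD-PM2.5 replicate 1 (0.0641), LL-FA replicate 1 (0.0798) or LL-PM2.5 replicate 1 (0.224), for macrophages without LD-FA replicate 1 (0.0565), LD-PM2.5 replicate 1 (0.102), LL-FA replicate 1 (0.714) or LL-PM2.5 replicate 1 (0.25), and for all 3 without LD-FA replicate 1 and LL-FA replicate 1 together (0.0568, 0.274 and 0.918). Erythroid markers passed on the higher side (adjusted p = 0.000385, and adjusted p = 0.366 with an estimated correlation), with a median of 0.52 that was 0.91 without LD-FA replicate 1 and 0.27 without LD-FA replicate 2, and 0 of 5 past the test adjusted over the list alone. Exocrine pancreas markers passed on the lower side (adjusted p = 9.39e-06, and adjusted p = 0.366 with an estimated correlation), and not without LD-FA replicate 1 (adjusted p = 0.516). The mean log2 level of each of the acute phase, heat shock and cytokine lists was lower in 16 of 16 pairs of a constant light and a light/dark library, by -1.04, -0.93 and -1.33 (exact permutation p = 0.0286 each, two-sided, adjusted p = 0.271 over 38 lists). Opposite phase clock genes had a median of -0.73, which was -0.27 without LD-PM2.5 replicate 2, with Arntl at -0.63 ± 0.10 and Nfil3 at -0.75 ± 0.12 past the test adjusted over the list alone (camera adjusted p = 8.95e-07, and adjusted p = 0.147 with an estimated correlation). edgeR called 0 of 11316 genes (smallest adjusted p 0.150), 641 had an unadjusted p under 0.05, and DESeq2 called 92, 15 up and 77 down. The count was 1 without LL-PM2.5 replicate 1 (Serpina12) and 1 without LL-PM2.5 replicate 2 (Hspa1b). Camera called 20 lists, 7 up and 13 down, against 14, 8 up and 6 down, for PM2.5 averaged over light. In a model of 2 groups the real split gave 16 lists, and 10 of 35 splits gave as many.

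The effects were also set against each other across the 11316 genes, which are not independent replicates. PM2.5 in the light/dark cycle and PM2.5 in constant light share no library, and their log2 fold changes correlated with a Pearson r of 0.366 (Spearman 0.148), where 100 simulations of unchanged groups gave -0.00015 ± 0.043 (SD). The simulations draw genes independently and leave out correlation between genes, so their SD may be too narrow to measure chance. The overlaps that follow have the same limit. Among genes with an unadjusted p under 0.05 in edgeR, 48 were higher in both against 16.3 given by independent draws, and 67 were lower in both against 12.8. Mtss1, Dbp and Rgs16 were higher and Arntl lower in both, as given above. Muscle markers were lower in both too, with medians of -9.22 and -9.20, being highest in LD-FA replicate 1 and LL-FA replicate 1. Without the listed markers of pancreas, muscle and fat the correlation was 0.348, which leaves in other transcripts of those tissues. The simulations set no library apart, so they cannot give such a shared difference. Over all tested genes the picture also moved with single libraries. The correlation ranged from 0.0262 without LL-FA replicate 1 to 0.530 without LL-PM2.5 replicate 2 and was 0.202 without LD-FA replicate 2, 0.247 without LD-PM2.5 replicate 1, 0.179 without LL-PM2.5 replicate 1 and 0.238 without LD-FA replicate 1 and LL-FA replicate 1. PM2.5 in the light/dark cycle and constant light in filtered air share the LD-FA libraries and correlated with r = 0.466 (Spearman 0.419), where the same simulation with shared controls gave 0.499 ± 0.0312. Their covariance of 0.0957 exceeded the simulated 0.0693 by 0.0264, and with 2 control libraries, of which each effect would keep only 1, the controls were not divided between the effects, so part of the excess may come from the shared libraries. This correlation was 0.282 without LD-FA replicate 1, 0.299 without LD-PM2.5 replicate 2, 0.0804 without LL-FA replicate 2 and 0.761 without LD-FA replicate 2.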

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

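The 6 tests of technical explanations in this part were chosen only after the results were seen, while the counts over other splits of the libraries were planned. Each of the 12 results here is a gene list whose response to PM2.5 differed between constant light and the light/dark cycle, by camera's test of the interaction at the preset correlation. With an estimated correlation none of the 12 passed, with adjusted p from 0.263 for erythroid genes to 0.914.

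Erythroid genes had a median log2 fold change with PM2.5 of -1.44 in the light/dark cycle and 1.06 in constant light (interaction adjusted p = 2.49e-16). The medians were -0.74 and -0.075 for cholesterol synthesis (4.46e-09), -0.91 and 0.34 for B and plasma cell markers (0.000437), and 0.36 and -0.39 for opposite phase clock genes (0.000448). These 4 calls held without each library in turn. For fatty acid oxidation and PPARa targets the medians were 0.11 and -0.25 (0.000245), with no call without LL-PM2.5 replicate 2 (adjusted p = 0.0765). For rhythmic outputs they were 0.90 and 0.25 (0.0139), with no call without LD-FA replicate 1 (0.0570), LD-PM2.5 replicate 2 (0.803) or LL-FA replicate 2 (0.0594). For heat shock genes they were 0.65 and 0.13 (0.0412), with no call without LD-FA replicate 2 (0.261), LD-PM2.5 replicate 2 (0.465), LL-FA replicate 2 (0.343) or LL-PM2.5 replicate 1 (0.796).

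The neutrophil genes S100a8 and S100a9 had medians of 1.08 and -0.45 (0.0119), and no call without LD-FA replicate 2 (0.0872), LD-PM2.5 replicate 2 (0.0941) or LL-PM2.5 replicate 1 (0.0667). Genes of DNA and histone methylation had medians of 0.25 and 0.011 (0.00589), and no call without LD-FA replicate 1 (0.0949), LD-PM2.5 replicate 1 (0.0516), LL-FA replicate 1 (0.0573) or LL-PM2.5 replicate 2 (0.0904). Periportal genes had medians of 0.019 and 0.26 (0.0492), and no call without LD-FA replicate 1 (0.0860), LD-FA replicate 2 (0.0764), LD-PM2.5 replicate 1 (0.373), LL-FA replicate 1 (0.465) or LL-PM2.5 replicate 2 (0.271). Exocrine pancreas markers (0.000139) lost their call without LD-FA replicate 1 (0.345) or LL-PM2.5 replicate 2 (0.572), and adipocyte markers (0.00160) without LL-FA replicate 1 (0.382), the libraries in which these markers are highest.

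The first pattern weighed is the higher level of E-box driven clock genes with PM2.5, Dbp and Per3 among them. Tissue from outside the liver is argued against for LD-FA replicate 1 and LL-FA replicate 1 only. Without these, the richest in muscle and in pancreas or fat, the list's mean log2 level was higher with PM2.5 by 1.10 ± 0.36 (SE). With all 8 libraries it was higher by 1.12 ± 0.28. The test leaves in LD-PM2.5 replicate 1 and LL-PM2.5 replicate 2, with pancreas markers, and LD-FA replicate 2, with muscle markers. It cannot decide on tissue in those libraries. Another clock time at collection could give the same picture and cannot be told apart from a response of the clock to PM2.5. Both explanations predict a lower opposite phase list, and it differed by -0.50 ± 0.27, which is under 2 SE. Its members did not move alike. With PM2.5 in the light/dark cycle 5 of 7 were positive, and in constant light 6 of 7 were negative. Collection times are not given, and the list decides for neither explanation. Both stay open, and the split between the LD-PM2.5 replicates in Nr1d1 (52.5 and 5.55 FPKM) and Cry1 (2.85 and 15.1) adds that samples of 1 group differed in clock genes.

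The second pattern is the lower level of acute phase genes in constant light, with Saa1, Saa2 and Orm2 in front. A smaller share of hepatocyte RNA is argued against, because hepatocyte markers differed by -0.0546 ± 0.0537 (SE) between constant light and light/dark while the acute phase list differed by -1.04 ± 0.16. Tissue from outside the liver in LD-FA replicate 1 and LL-FA replicate 1 is argued against too, as the difference was -0.93 ± 0.17 without both. Tissue in the other libraries, such as pancreas in LD-PM2.5 replicate 1 and LL-PM2.5 replicate 2, stayed in and cannot be judged by this test. An inflammatory state of single animals in the light/dark groups was not tested, and Saa1 ranged from 303 to 2851 FPKM among them. A response to constant light may explain the pattern and remains a hypothesis, found and tested on the same libraries.

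The third pattern is pancreas and muscle transcripts in single libraries. The 7 pancreas markers, Cela2a and Prss2 among them, stood in LL-PM2.5 replicate 2 at a median log2 ratio of -3.44 to LD-FA replicate 1, with an SD over markers of 0.209, as 1 tissue present in different amounts would give. Pancreas collected with the liver is a candidate explanation. Reads of LD-FA replicate 1 leaking into the other library are argued against, because at the pancreas share of 9.61% the muscle markers reached only 3.02% of the FPKM such reads would bring. No biological explanation was tested for this pattern.

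Splits of the 8 libraries into 4 and 4, 35 with the real one, which the counts include, were tested with edgeR in a model of 2 groups. Chance cannot be excluded by this count for PM2.5 averaged over light, where the real split called 1 gene (Mtss1) and 2 splits gave as many, the highest other 3. That other split is constant light against light/dark, a real factor of the design, and the remaining splits called 0. For constant light averaged over air the real split called 3 genes (Cyp26a1, Dnajb1 and Prg4) in this model. No other split gave as many and the highest other gave 1, which met the limit set in advance for excluding chance. Rank 1 among 35 is the most this count can give, and it rests on 3 genes. The main fit of 4 group means called 0 genes for this average (smallest edgeR adjusted p 0.150). Chance is therefore not taken as excluded here. At an unadjusted p under 0.05 it cannot be excluded for either, with 1145 genes for PM2.5 (5 splits with as many) and 521 for constant light (15 splits with as many), and 2193 in the highest other. That split sets both LD-FA libraries, LL-FA replicate 2 and LL-PM2.5 replicate 2 against the rest, and a structure of the samples that crosses the groups could give its count, which was not tested. Nor can chance be excluded for the lists past camera, 13 for PM2.5 (20 splits with as many) and 16 for constant light (10 splits with as many), with 21 in the highest other.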

How the results depend on the processing

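DESeq2, limma with a trend on log2(FPKM + 1), the robust prior, the fit without LD-FA replicate 1 and LL-FA replicate 1, and the permutation of list scores were chosen only after the results were seen. The other alternatives were planned, and all of them were run. Values named for single genes were set against part of the alternatives. These were a pseudocount of 0.1, quantile normalization, median-of-ratios scaling and the replicate block. To them came leaving out each library, and leaving out LD-FA replicate 1 and LL-FA replicate 1 together. Changes of the filter or variance model, array weights, limma with a trend, DESeq2 and the fit of only the groups compared were not included. Nor were list members' values for both exposures, the interaction or the averages, unless named by rule or past the threshold. First come those included alternatives that keep each library, and the fit without LD-FA replicate 1 and LL-FA replicate 1. Under them 824 pairs of a value and an alternative kept direction and side of the threshold, 4 were no longer past it and 2 reversed. Calls lost or gained under the alternatives not included are given below. With 1 library left out, 1301 pairs kept both, 14 came past the threshold, 11 no longer passed it and 2 reversed. Only Rgs16 and Mtss1 had passed the threshold over all genes, so for the other genes keeping the side says little. The reversals in these counts were for PM2.5 in the light/dark cycle, and clock genes past no test are counted only for PM2.5 in either light regime. Nr1d1 was -0.29 with a pseudocount of 0.1, -0.20 with quantile normalization and ran from -1.93 without LD-PM2.5 replicate 1 to 1.35 without replicate 2. Cry1 ran from -0.81 without LD-PM2.5 replicate 2 to 1.71 without replicate 1. The LD-PM2.5 replicates lie far apart in these 2 genes. Clock genes also turned outside these counts, as Nr1d1 from 0.99 to -0.22 without LD-PM2.5 replicate 1 and Cry1 from 0.18 to -0.70 without LD-PM2.5 replicate 2 for PM2.5 averaged over light, Ciart from -0.98 to 1.09 without LD-PM2.5 replicate 2 for the interaction, Per1 from -0.45 to 0.66 without LD-PM2.5 replicate 2 for constant light in PM2.5 and Per2 from -0.016 to 0.76 without LD-FA replicate 2 for constant light in filtered air.

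Counts of genes past the threshold depended on the filter and the tool. Without a filter edgeR called 647 genes for PM2.5 in the light/dark cycle, 201 for constant light in filtered air, 476 for PM2.5 in constant light, 358 for constant light in PM2.5, 486 for both exposures, 239 for the interaction, 696 for PM2.5 averaged over light and 291 for constant light averaged over air. Of these 513, 141, 297, 319, 358, 199, 472 and 251 also belong to the 11316 genes that pass the filter. With 23030 genes in that fit the prior degrees of freedom were 76.3, against 3.46 in the fit with the filter and 3.12 with the stricter filter, so each gene's variance was drawn further toward the trend. DESeq2 called 151, 43, 58, 139, 95, 33, 161 and 92 in the same order, and the cause of its higher counts was not tested.

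Smaller changes in counts came from single genes, chosen after their values were seen. Quantile normalization, array weights and limma with a trend each called 1 gene (Rny3) for PM2.5 in constant light, for constant light in PM2.5 and for constant light averaged over air, and 2 (Rny3 and Gm23245) for the interaction. Rny3 is listed at 0 in 6 libraries and at 9.16 and 9.78 FPKM in LL-PM2.5. For both exposures quantile normalization and limma with a trend called 1 (Rny3), array weights 2 (Rny3 and Dbp), the stricter filter 2 (Arntl and Dbp) and the robust prior 1 (Arntl). For PM2.5 in constant light the robust prior called 1 (Rgs16). For PM2.5 averaged over light a pseudocount of 0.1 called 1 (Mtss1), no variance trend 1 (Rgs16), the robust prior 3 (Arntl, Mtss1 and Rgs16), quantile normalization, array weights and limma with a trend each 2 (Mtss1 and Rny3, without Rgs16), the stricter filter 0 and the fit without LD-FA replicate 1 and LL-FA replicate 1 also 0, where Rgs16 lies under the stricter filter. Without those 2 libraries 1 gene (Acta1) was called for PM2.5 in the light/dark cycle. The cause was not tested for the others. Array weights were 1.62 in LD-FA, 0.967 in LD-PM2.5, 0.847 in LL-FA and 0.752 in LL-PM2.5, equal within each group by construction.

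With an estimated correlation, over 0.01 in lists named earlier, camera called 0 lists in all 8 comparisons. The adjusted p was then 0.579 for E-box genes with PM2.5 in the light/dark cycle and 0.254 in constant light, 0.254 for opposite phase genes with PM2.5 in constant light, 0.155 and 0.263 for acute phase genes under constant light in filtered air and in PM2.5, and 0.290 and 0.310 for heat shock genes there. The correlation of PM2.5 effects between light regimes was 0.246 with a pseudocount of 0.1, 0.308 without a filter, 0.314 with the stricter filter, 0.155 with quantile normalization and 0.238 without LD-FA replicate 1 and LL-FA replicate 1. The cause was not tested.

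Leaving out each library in turn gave 0 to 36 genes for PM2.5 in the light/dark cycle, 0 to 0 for constant light in filtered air, 0 to 10 for PM2.5 in constant light, 0 to 4 for constant light in PM2.5, 0 to 7 for both exposures, 0 to 0 for the interaction, 0 to 17 for PM2.5 averaged over light and 0 to 1 for constant light averaged over air. The highest counts came without LD-PM2.5 replicate 1 (36 and 17 genes) or LL-PM2.5 replicate 1 (10, 4 and 7). Lists past camera numbered 11 to 17, 15 to 22, 11 to 19, 10 to 18, 12 to 24, 11 to 16, 10 to 16 and 17 to 22 in the same order. The correlation of PM2.5 in the light/dark cycle with constant light in filtered air ran from 0.0804 (without LL-FA replicate 2) to 0.761 (without LD-FA replicate 2), and that with PM2.5 in constant light from 0.0262 (without LL-FA replicate 1) to 0.530 (without LL-PM2.5 replicate 2).

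With the replicate number as a block no count of genes changed, and Rgs16 and Mtss1 had an adjusted p of 0.0499 for PM2.5 averaged over light. Lists past camera with the block numbered 14, 19, 15, 14, 19, 16, 16 and 20. The difference between replicates 1 and 2 correlated between groups at 0.33 (LD-FA with LD-PM2.5), 0.22 (LD-FA with LL-FA), -0.59 (LD-FA with LL-PM2.5), 0.01 (LD-PM2.5 with LL-FA), -0.26 (LD-PM2.5 with LL-PM2.5) and 0.06 (LL-FA with LL-PM2.5). The signs differ, so the replicate number does not mark a common effect in all groups. Values such as -0.59 leave open a structure shared by libraries of different groups, and batches are not given. At this depth, genes such as Rgs16, at 0.0880 to 3.30 FPKM, lie near the filter, and changes of 2-fold were recovered in 28.4% of simulated genes between groups of 2.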

Other observations

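No test in this part was chosen after its result was seen except the permutation of list scores and the fit without LD-FA replicate 1 and LL-FA replicate 1. Genes that write and erase histone acetylation, the list nearest to the chromatin question of the series, passed camera in 0 of 8 comparisons. Over 23 measured members, among them Hdac3, Sirt1 and Ep300, the median log2 fold change lay between 0.0049 and 0.11 in all 8 comparisons, with a smallest camera adjusted p of 0.593 and 0 members past the test adjusted over the list alone. With members on both sides of 0, a median cannot show that single members stayed unchanged. Genes of DNA and histone methylation passed camera in 3 comparisons, with 18 measured members and medians from -0.26 to 0.25. For PM2.5 in the light/dark cycle 14 of the 18 were positive with 0 past the test adjusted over the list alone (camera adjusted p = 0.00481, and adjusted p = 0.655 with an estimated correlation), and the call ended without LD-FA replicate 1 (adjusted p = 0.0963) or LD-PM2.5 replicate 1 (0.0603).

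Targets of the aryl hydrocarbon receptor, which senses combustion products such as those carried by particles, passed camera in 0 of 8 comparisons. Over 5 measured members the medians ran from -0.36 to 0.18, with a smallest adjusted p of 0.203, and Cyp1a1, its best known target, lay between 0.155 and 0.532 FPKM and under the filter. The other lists with 0 calls in camera were bile acid synthesis and transport (medians -0.11 to 0.00014, smallest adjusted p 0.584), CAR and PXR targets (-0.13 to 0.18, 0.180), cell cycle (-0.22 to 0.19, 0.364), hepatocyte (-0.11 to 0.14, 0.143), sinusoidal endothelium (-0.12 to 0.017, 0.129), stellate cell and fibroblast (-0.15 to 0.19, 0.403) and gut and gallbladder epithelium (-0.41 to 0.49, 0.0927). NRF2 antioxidant genes, which respond to oxidative stress, had a median of 0.11 for constant light averaged over air, with 10 of 16 positive and 0 past the test adjusted over the list alone (camera adjusted p = 0.00418, and adjusted p = 0.226 with an estimated correlation). The median was 0.041 without LD-PM2.5 replicate 2, and the call ended without LD-FA replicate 1 and LL-FA replicate 1 together (adjusted p = 0.119). Their mean log2 level was higher by 0.18 in 16 of 16 pairs of a constant light and a light/dark library (exact permutation p = 0.0286, two-sided, adjusted p = 0.271), and their median with PM2.5 averaged over light was 0.02 (camera adjusted p = 0.801).

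Unfolded protein response genes, which restore folding in the endoplasmic reticulum, had medians of opposite sign for constant light and PM2.5. Their median was -0.37 for constant light averaged over air (camera adjusted p = 8.32e-08, and adjusted p = 0.375 with an estimated correlation) and 0.45 for PM2.5 averaged over light (camera adjusted p = 2.14e-05, and adjusted p = 0.702 with an estimated correlation), over 20 measured members, of which 0 and 1 passed the test adjusted over the list alone. The first was -0.24 without LD-PM2.5 replicate 1, -0.23 without LL-PM2.5 replicate 1 and -0.69 without LL-PM2.5 replicate 2, and the call of the second ended without LL-PM2.5 replicate 2 (adjusted p = 0.141). Female-biased liver genes had a median of 1.01 with PM2.5 averaged over light (camera adjusted p = 2.14e-05, and adjusted p = 0.30 with an estimated correlation), which was 0.62 without LL-PM2.5 replicate 2, and 1 of the 4 measured members, Acot3 at 1.53 ± 0.31, rose adjusted over the list alone. The sex of the mice is not given in the sources used here. Across the tested genes the first 3 principal components held 35.8%, 27.7% and 12.6% of the variance. Libraries of a group stood apart on them. On component 1 LD-FA replicates 1 and 2 were at -55.6 and -1.73. On component 2 LL-FA replicates 1 and 2 were at -41.0 and -6.78, and those of LL-PM2.5 at -9.08 and 38.1.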
